A study of Homo sapiens with 11 samples.

How the data were processed

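RNA was measured by high-throughput sequencing in 11 tumour samples from a patient-derived xenograft model of human pancreatic cancer carried in nude mice. The series' design text instead describes cultured cells exposed for hours, and the sample labels were followed. The mice received YKL-5-124, an inhibitor of the kinase CDK7, at 10 mg/kg, or only its vehicle, which held 5% DMSO and 95% D5W. The labels name 3 groups: vehicle (n = 3), YKL-5-124 for 3 days (n = 3) and YKL-5-124 resistant (n = 5), for which no day is given. Labels do not say whether each sample came from a separate animal, so the p-values may measure only the spread between these samples. The column names of 4 of the 5 resistant samples share a leading number whose meaning the labels do not state, so it was not used as a factor. Replicate numbers were checked as a possible pairing by correlating samples' deviations from their group means. With the same number, r was 0.025 to 0.097 in 3-day against vehicle, where other pairs reached 0.080. It was 0.046 to 0.080 in resistant against vehicle (others at most 0.032) and -0.084 to -0.0018 between resistant and 3-day. The check was weak and mixed, so a pairing was neither shown nor excluded, and the samples were treated as unpaired.

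The deposited file holds counts per gene, 1 column per sample, which the authors did not normalise: the values are whole numbers with a different total in each sample. Beside them the deposited file gives each gene's length in bases, which is not a measurement of these samples. The submitters' notes name STAR 2.6.1d, featureCounts 1.5.0-p3 and DESeq2 1.24.0, with the genome build GRCh38, without giving the role of each. Library type, strandedness and any removal of mouse reads are not given in the sources used here, so overlapping antisense genes and reads from the host cannot be separated. Gene identifiers, names, biotypes and coordinates came with the file. Chromosome, start, end and strand matched GENCODE 29 for 58735 of 58735 genes.

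The file held 58735 genes, of which 35068 had at least 1 count. Total counts per sample ran from 13238482 to 19083797, a ratio of 1.44. Genes with too few counts were removed by the filterByExpr function by group, which left 18040 genes, 13822 of them protein-coding. Libraries were scaled by the trimmed mean of M-values (TMM), and values are given as CPM (counts relative to the scaled library size, as edgeR computes them) on the scaled library sizes. A prior count of 2 was added for log2 CPM values. Log2 fold changes came from edgeR's fit with its own default prior count instead.

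The main test was edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) on all 11 samples in 1 fit with the 3 groups as means and no covariate. That fit takes a gene's spread to be the same in all groups. Genes with a Benjamini-Hochberg adjusted p under 0.05 were called, with no minimum fold change. Standard errors (SE) of log2 fold changes were derived from the fold change and its F statistic, and errors of CPM are standard deviations (SD). The 3 comparisons were 3-day against vehicle, resistant against vehicle and resistant against 3-day. The last also tests the difference between the changes of both treated groups from vehicle. The first pair shares the vehicle libraries, which alone makes their fold changes resemble each other, so their covariance was set against 20 simulations of unchanged groups.

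Before the data were examined, 44 gene lists were written from general knowledge, 33 of pathways or complexes and 11 of cell types that a tumour in a mouse could hold. The 39 lists with at least 5 tested members were tested by camera (limma 3.58.1), which compares a list with all other genes, with a preset correlation between genes of 0.01 and adjustment over the lists of a comparison. Each test was repeated with a correlation estimated per list, and with fry, which asks whether a list's genes move one way. Both used all 11 samples in every comparison, so the spread of the group outside a comparison enters them. For each list, the number of called members is given over all genes and adjusted over the list alone.

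Genes named in the text followed a rule fixed before the data were examined. It took 10 genes of the drug target complex, drug efflux and proliferation in every comparison. It also took, per comparison, the 8 largest rises and 8 largest falls among called protein-coding genes with at least 5 CPM in the higher group and no overlap between groups. From each called list it took the 3 called members with the smallest p in the list's direction and 1 against it. Genes on chromosome Y and XIST were left out of every result. TNS3, ARHGEF10L and MSC, the 3 genes called in opposite directions in both treated groups, and COL1A1, COL1A2, COL3A1, DCN and SPARC were chosen after their values were seen.

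Composition was measured per library as the share of counts in the 50 most abundant genes, in mitochondrially encoded genes and in pseudogenes, and as summed CPM of each cell type list. These summed CPM were relative to total counts without TMM scaling. Groups were compared by exact permutation tests, 2-sided, adjusted over 48 tests. The smallest p such a test can give is 0.1 with 3 against 3 samples and 0.0357 with 3 against 5. In the resistant group, 142 values were tested for a sample far from the others by Dixon's ratio with a critical value of 0.710, on log2 CPM for genes and on CPM for summed markers. Differences between the changes of both treated groups were listed for a closer look only for genes named in a comparison with vehicle and called there, and the 3 called in both, where the changes had opposite signs, since differences of size alone are the comparison of resistant with 3-day tumours.

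The pipeline was tested on simulated data with known changes and the same spread in all groups. In groups of these sizes it called 23.5% of genes changed by 1 on the log2 scale and 60.4% of those changed by 2 in the 3-day comparison, with 4 false calls among 17380 unchanged genes. In the comparison of resistant with vehicle it called 30.6% and 72.9%. A list of 30 genes shifted by 0.5 gave a camera p of 4.06e-14 with the preset correlation and 1.33e-04 with the estimated one. Of 100 unshifted lists, 1 gave p under 0.05.

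Alternatives were DESeq2-type size factors, upper quartile scaling, the DESeq2 1.42.0 Wald test, no filter, a stricter filter (1 CPM in at least 3 samples), protein-coding genes only, a minimum log2 fold change of 1, only the 2 compared groups in the fit, the replicate number as a block, and each library left out in turn. Resistant replicates 2 and 4 were also left out together, an alternative chosen after seeing the data. Other splits of the samples were counted for each comparison. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used for tables and plots. For a gene with no counts in a group, the floor was 3 counts over the group, and intervals and floors cover counting error only.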

Results

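The data are gene expression counts from 11 pancreatic cancer xenograft tumour samples in 3 groups. Total counts were 17296005, 15970793 and 16635197 in vehicle replicates 1 to 3, and 13238482, 17208785 and 15091317 in 3-day replicates 1 to 3. In resistant replicates 1 to 5 they were 17861702, 19083797, 17724073, 15711212 and 16667298. The median SD of a gene's log2 CPM within a group was 0.173 in vehicle, 0.269 in 3-day and 0.404 in resistant tumours. The first principal component held 24.2% of the variance and the second 18.8%. Resistant replicate 4 stood apart on components 2 and 3, at -62.1 and -72.2 against -27.5 to 8.51 and -9.04 to 35.9 in the other resistant libraries. Of the 50 most abundant genes, the share of counts was 16.7 ± 0.237% (SD, n = 3) in vehicle, 19.6 ± 1.08% (n = 3) in 3-day and 18.1 ± 0.766% (n = 5) in resistant tumours.

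The first comparison asked which genes differed after 3 days of CDK7 inhibition. Genes that copy DNA and drive mitosis were lower in 3-day tumours (13 of 43 and 11 of 35 called), as were genes of the cytosolic ribosome (13 of 45), while replication-dependent histone genes (7 of 23) and genes of the hypoxia response (5 of 28) were higher. With an estimated correlation these 5 camera calls were lost, with an adjusted p of 0.433 for histone genes and 0.593 for each other list. In the fry test mitosis (adjusted p = 0.0900) and hypoxia (0.188) missed the threshold too. The estimated correlation drew on resistant samples as well. The SD of the DNA replication list mean was 0.0390 in vehicle, 0.0225 at 3 days and 0.359 in resistant tumours. For ribosomal protein genes it was 0.0381, 0.245 and 0.284. How far the resistant spread caused these losses was not tested. Of 43 DNA replication and E2F target genes, all 43 had a lower mean and 13 fell, with a list median log2 fold change of -0.79. Of 45 ribosomal protein genes all 45 had a lower mean and 13 fell, with a median of -0.63. CDKN1A, the cell cycle inhibitor p21, rose from 107 ± 5.64 CPM (SD, n = 3) to 201 ± 27.2 CPM (n = 3), a log2 fold change of 0.92 ± 0.20 (SE). E2F1, a transcription factor of S phase genes, fell from 47.3 ± 2.23 to 27.0 ± 3.06 CPM (n = 3 each), a log2 fold change of -0.81 ± 0.16.

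In all, 412 genes were called higher and 447 lower at 3 days by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, of 18040 tested. DESeq2's Wald test gave 882 and 920, and a fit of only these 2 groups gave 1978 and 2080, with 851 of the 859 calls kept. An unadjusted p under 0.05 was found for 4189 genes. Groups did not overlap for 858 of the 859 called genes and for 40.4% of all tested genes, against the 10% that chance gives. CDKN1A (ENSG00000124762, GRCh38 chromosome 6, 36676460 to 36687339) had an adjusted p of 0.0277 and E2F1 (ENSG00000101412, chromosome 20, 33675683 to 33686404) one of 0.0194 in that edgeR test. Without vehicle replicate 1, 2 or 3, 18, 1 and 20 of the 859 calls remained, and without 3-day replicate 1, 2 or 3, 121, 405 and 20 remained. All 859 kept their sign in every one of those fits, in which a group of 2 libraries has less power by construction. Where groups do not overlap, as for 858 of them, leaving out a library can hardly turn a sign. The kept signs are therefore no separate support. Summed CPM of macrophage and myeloid markers was 164 ± 32.6 in vehicle and 96.9 ± 25.6 at 3 days (n = 3 each), that of endothelial markers 65.6 ± 2.68 and 49.8 ± 3.66, of pancreatic acinar markers 3.18 ± 0.581 and 8.48 ± 1.91, of endocrine markers 6.79 ± 1.96 and 12.5 ± 1.08 and of erythroid markers 0.121 ± 0.0614 and 0.654 ± 0.449. Each of these had an exact permutation p of 0.1, the smallest such a test can give, adjusted 0.282. All 5 myeloid markers had a lower mean, with a fry adjusted p of 0.0411 and a camera adjusted p of 0.222. Endothelial markers did not fall as a list. Their mean log2 CPM over 8 tested members, relative to vehicle, was 0.33, 0.43 and 0.01 in 3-day replicates 1 to 3.

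The drug target itself did not pass the test. CDK7 (ENSG00000134058, chromosome 5, 69234795 to 69277430) was at 33.4 ± 3.06 CPM (n = 3) in vehicle, 28.99 ± 2.67 (n = 3) in 3-day and 32.4 ± 6.55 (n = 5) in resistant tumours. Its log2 fold change at 3 days was -0.20 ± 0.18 with an edgeR adjusted p of 0.551, and its 95% interval ran from -0.60 to 0.20. Its partners in the CDK-activating kinase, CCNH and MNAT1, had log2 fold changes of 0.21 ± 0.15 and -0.46 ± 0.22 (adjusted p = 0.455 and 0.240). The list of TFIIH and CDK-activating kinase genes was not called in any comparison, with camera adjusted p of 0.827, 0.726 and 0.910. MYC was at 89.3 ± 11.9 CPM in vehicle and 92.7 ± 23.4 in 3-day tumours, a log2 fold change of 0.05 ± 0.31. Its sign turned without vehicle replicate 1 (-0.01), vehicle replicate 2 (-0.01) or 3-day replicate 1 (-0.12). In resistant tumours MYC was at 52.3 ± 21.0 CPM (n = 5), with log2 fold changes of -0.77 ± 0.27 against vehicle and -0.82 ± 0.27 against 3-day and edgeR adjusted p of 0.139 and 0.0746. It was called lower against vehicle with no filter (edgeR adjusted p = 0.0127), and against 3-day with no filter (0.00621) and by DESeq2 (0.0317). The drug efflux pumps ABCB1 and ABCG2 were below 1 CPM on average in all 3 groups, too low for a difference to be read at this depth.

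Among genes of the replication machinery, GINS3, a subunit of the replicative helicase complex, fell from 12.02 ± 1.20 to 3.56 ± 0.311 CPM, a log2 fold change of -1.75 ± 0.28 (edgeR adjusted p = 0.0106). The helicase subunit MCM6 fell by 1.28 and the sliding clamp PCNA fell by 1.14 on the log2 scale. Adjusted over the list alone, 33 of the 43 genes were lower. Of 35 mitosis and G2/M genes 11 fell and 24 did not pass the test, and 26 were lower adjusted over the list alone. CDK1, the mitotic kinase, fell by 0.91, the checkpoint kinase BUB1 fell by 0.84 and the kinetochore protein NUF2 fell by 1.08. MKI67, a marker of proliferating cells, was at 613 ± 38.6 CPM in vehicle and 305 ± 68.5 at 3 days (n = 3 each), with an edgeR adjusted p of 0.0573, and CCNB1 had one of 0.0653. DESeq2's test called both, with adjusted p of 0.00975 for MKI67 and 0.0221 for CCNB1. Camera adjusted p was 3.11e-16 for DNA replication and 5.31e-14 for mitosis. With an estimated correlation the adjusted p was 0.593 for both lists.

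Genes of DNA repair were lower as well. Of 31 homologous recombination and Fanconi anaemia genes, 7 fell and none rose, with NBN at -0.88 ± 0.15, RAD51D at -1.08 ± 0.20 and FANCE at -1.34 ± 0.30 (log2 fold change, SE). With p adjusted over the list alone, 16 were lower and 1 was higher. Of 25 replication stress checkpoint genes, the kinase gene CHEK1 fell by 0.73 and TIMELESS fell by 0.88, with 6 lower and 1 higher adjusted over the list alone. By camera, the adjusted p was 2.99e-07 and 0.00156, and with an estimated correlation the adjusted p was 0.593 for both. The checkpoint list had a fry adjusted p of 0.119.

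Replication-dependent histone genes were higher at 3 days: 7 of 23 rose, 22 had a higher mean, and the list median was 1.26. HIST1H2BK rose from 47.7 ± 4.30 to 140 ± 18.0 CPM, a log2 fold change of 1.55 ± 0.24 (edgeR adjusted p = 0.0104). HIST1H2BC and HIST1H4I rose by 1.93 ± 0.30 and 1.55 ± 0.25. These genes share sequence with near-identical copies, so which copy rose is uncertain. When p was adjusted over the list alone, 12 were higher. In the camera test the adjusted p was 1.60e-10, and 0.433 with an estimated correlation. Transcripts of these genes mostly lack a poly(A) tail, and the type of library is not given in the sources used here.

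Cytosolic ribosomal protein genes were lower, with RPS20 falling from 729 ± 5.01 to 341 ± 54.1 CPM, a log2 fold change of -1.096 ± 0.16 (edgeR adjusted p = 0.00909). RPS4X and RPS3 had log2 fold changes of -1.02 ± 0.19 and -1.239 ± 0.24, and adjusted over the list alone 35 of the 45 genes were lower. Camera adjusted p was 1.92e-19, and 0.593 with an estimated correlation. In the list of MYC targets and ribosome biogenesis 1 of 30 genes fell, the RNA polymerase I subunit POLR1B at -0.86 ± 0.21, and adjusted over the list alone 3 were lower. Its camera adjusted p was 0.0167, 0.593 with an estimated correlation and 0.0810 without 3-day replicate 3.

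Genes of hypoxia and glycolysis were higher, with 5 of 28 rising and 10 higher adjusted over the list alone. EGLN3, an oxygen-sensing hydroxylase, rose by 1.48 ± 0.25, PFKFB3 by 1.46 ± 0.28 and the glycolytic enzyme gene PFKP by 0.77 ± 0.16 on the log2 scale. By camera, the adjusted p was 3.34e-05, and 0.593 with an estimated correlation. Of 23 YAP/TEAD target genes 4 rose and 1 fell. CYR61 rose from 89.6 ± 12.7 to 406 ± 122 CPM, AMOTL2 and NUAK2 rose by 0.95 ± 0.15 and 1.34 ± 0.27, and ANKRD1 went the other way at -2.70 ± 0.66. Adjusted over the list alone, 9 were higher and 3 lower. In the camera test the adjusted p was 6.34e-04, and 0.433 with an estimated correlation. Immediate early genes were higher as a list (median 0.67, 18 of 20 above 0) with no single call and 5 higher adjusted over the list alone. Its camera adjusted p was 6.34e-04, and 0.593 with an estimated correlation, and its fry adjusted p was 0.188.

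Of single genes outside the lists, the largest rises were in ZBP1, a sensor of Z-form nucleic acids, at 4.81 ± 1.04, FAM131B at 2.86 ± 0.39 and the endocytic receptor CUBN at 2.80 ± 0.34 (log2 fold change, SE). FAM131B (ENSG00000159784, chromosome 7, 143353400 to 143362770) rose from 1.01 ± 0.317 to 7.37 ± 0.252 CPM. SELPLG, TG, NNAT, SLC2A9 and OVGP1 rose by 2.31 to 2.72. FYB1 fell by 4.47 ± 1.02, and ID3, an inhibitor of basic helix-loop-helix factors, fell by 4.32 ± 0.99. ID3 (ENSG00000117318, chromosome 1, 23557918 to 23559794) went from 40.6 ± 10.5 to 2.003 ± 1.36 CPM (n = 3 each). SCUBE3, a secreted protein gene, went from 466 ± 41.5 to 56.0 ± 9.70 CPM, and PLEKHS1, WISP1, PRDM16 and RTL9 fell as well, at -4.04, -3.84, -3.08 and -2.76. All of these passed edgeR's test with adjusted p between 0.00515 and 0.0464.

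**Figure D1:**
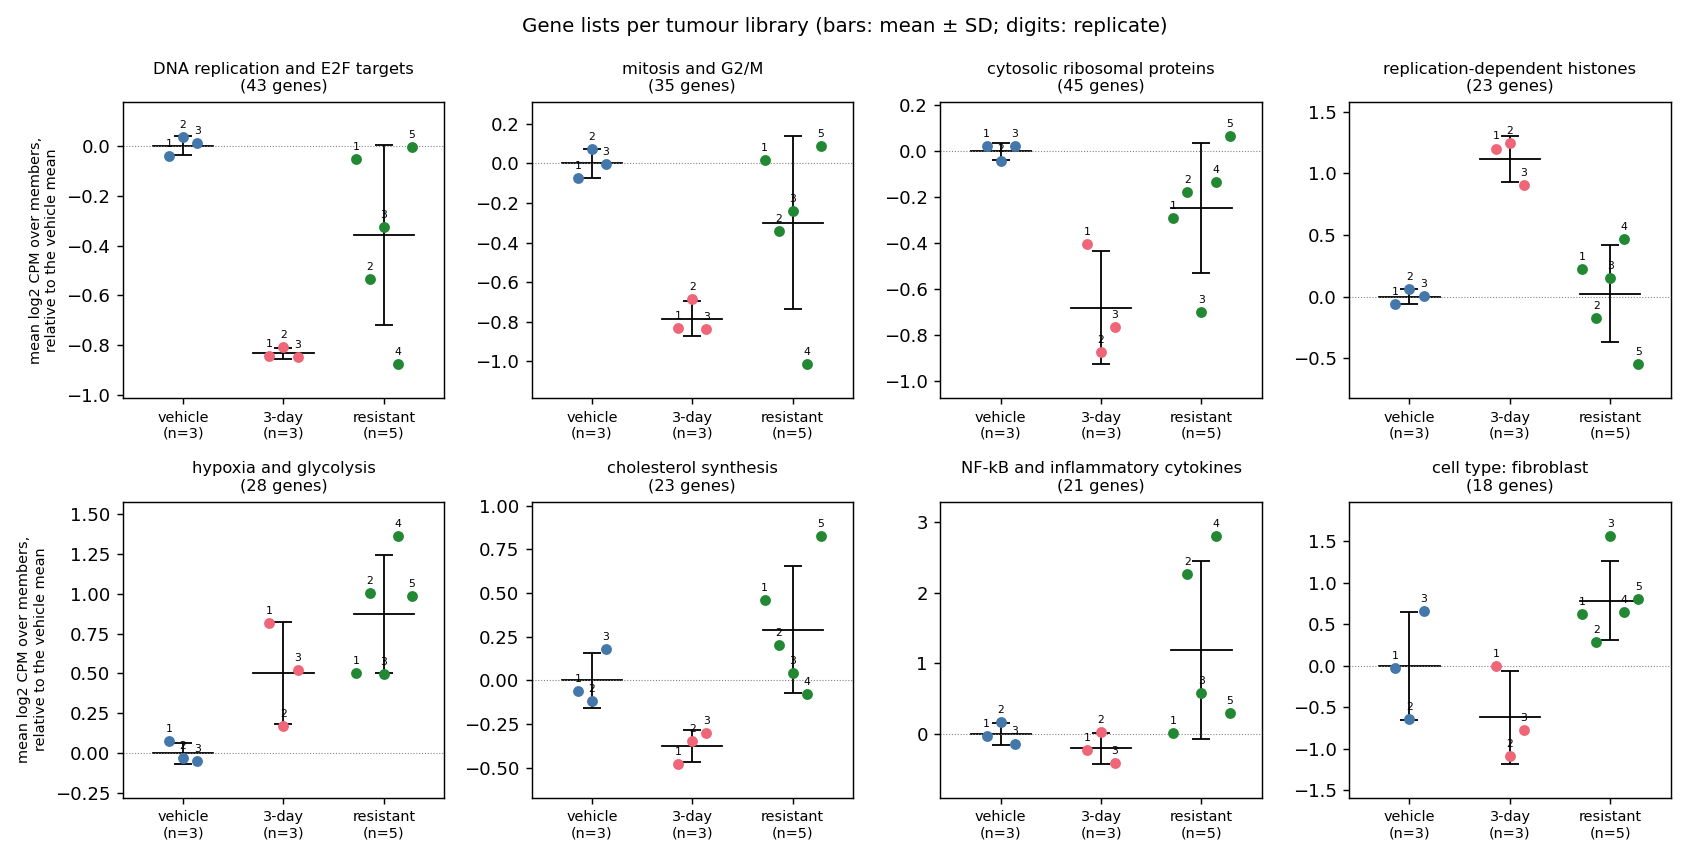
Mean log2 CPM over the members of 8 gene lists in each tumour library, relative to the vehicle mean (vertical axes), by group (horizontal axes); points are libraries with their replicate number and bars are mean ± SD. The 3-day libraries lie at -0.85 to -0.81 for DNA replication, whereas the resistant libraries spread from -0.87 to 0.00.

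The second comparison asked how tumours described as resistant to the drug differed from vehicle-treated ones. Genes of hypoxia and glycolysis were higher in resistant tumours, with 11 of 28 rising, as were mesenchymal genes (3 of 19), NRF2 target genes (3 of 23) and fibroblast marker genes (3 of 18). These 4 camera calls were lost with an estimated correlation, with an adjusted p of 0.318 each. Fibroblast markers missed the threshold by fry too (adjusted p = 0.0896). PFKFB3, an activator of glycolysis, rose from 49.9 ± 4.58 (SD, n = 3) to 216 ± 21.6 CPM (n = 5), a log2 fold change of 2.11 ± 0.27 (SE). CDKN1A was higher again, at 223 ± 58.1 CPM (n = 5) against 107 ± 5.64 (n = 3), a log2 fold change of 1.07 ± 0.19. E2F1 was at 44.2 ± 6.58 CPM and did not pass the test, with a log2 fold change of -0.10 ± 0.14 and a 95% interval from -0.41 to 0.21.

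In this comparison 313 genes were called higher and 204 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 3557 had an unadjusted p under 0.05. DESeq2's Wald test gave 875 and 461, and a fit of only these 2 groups gave 171 and 114, with 265 of the 517 calls kept. CDKN1A had an adjusted p of 0.0139 and PFKFB3 one of 0.00527. Without vehicle replicate 1, 2 or 3, 51, 1 and 53 of the 517 calls remained, and without a resistant replicate 386 to 488 did. Without resistant replicate 4 the number called lower was 309. Leaving out resistant replicates 2 and 4 together, chosen after seeing the data, gave 401 higher and 399 lower. Fibroblast markers moved with this grouping: their summed CPM was 6230 ± 742 in vehicle (n = 3), 5807 ± 1523 in 3-day (n = 3) and 12171 ± 2936 in resistant tumours (n = 5; exact permutation p = 0.0357 against vehicle, adjusted 0.282). Pancreatic acinar markers, at 3.18 ± 0.581 in vehicle and 13.5 ± 4.96 in resistant tumours, and Schwann and neural markers, at 229 ± 21.4 and 336 ± 40.8, had the same exact and adjusted p. Most of the fibroblast sum came from COL5A1 and COL1A1. On scaled library sizes these were at 2941 and 2098 CPM in vehicle and 6441 and 3766 in resistant tumours.

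In the hypoxia and glycolysis list, EGLN3 rose by 1.68 ± 0.24 and ADM, a vasodilator peptide gene, by 2.68 ± 0.44 on the log2 scale. With p adjusted over the list alone, 19 were higher. Camera adjusted p was 7.52e-13, and 0.318 with an estimated correlation. Mesenchymal transition genes held 3 of 19 calls, all higher: the integrin genes ITGA5 at 1.11 ± 0.21 and ITGB3 at 0.94 ± 0.23, and LOXL2, which crosslinks collagen, at 0.78 ± 0.19. When p was adjusted over the list alone, 5 were higher, with camera adjusted p of 8.86e-04 and 0.318 with an estimated correlation. LOXL2 lost its call under upper quartile scaling (adjusted p = 0.0508).

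NRF2 target genes, which handle oxidative stress and iron, included 3 rises among 23: the ferritin genes FTL at 0.71 ± 0.15 and FTH1 at 1.13 ± 0.25, and AKR1C3 at 1.11 ± 0.25. Adjusted over the list alone, 4 were higher. By camera, the adjusted p was 7.92e-04, and 0.318 with an estimated correlation. YAP/TEAD targets held 4 rises among 23, with F3, the tissue factor gene, from 91.2 ± 16.9 to 442 ± 185 CPM, NUAK2 at 1.53 ± 0.25 and WWC1 at 1.03 ± 0.23. With p adjusted over the list alone, 6 were higher and 1 lower, with camera adjusted p of 0.00531 and 0.318 with an estimated correlation.

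Fibroblast markers held 3 rises among 18 tested. COL5A1 (ENSG00000130635, chromosome 9, 134641774 to 134844843), a fibrillar collagen gene, rose from 2941 ± 392 to 6441 ± 1873 CPM, a log2 fold change of 1.13 ± 0.28 (edgeR adjusted p = 0.0466). COL6A3 and LUM rose by 1.83 ± 0.37 and 3.05 ± 0.64. The list means of resistant replicates 1, 2 and 4 (0.62, 0.29 and 0.65) lay within the vehicle range, -0.64 to 0.66. When p was adjusted over the list alone, 6 were higher, with camera adjusted p of 0.00106 and 0.318 with an estimated correlation. COL1A2, another collagen gene abundant in fibroblasts, was at 2.25 ± 1.98 CPM in vehicle and 0.255 ± 0.481 in resistant tumours.

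NF-kB and inflammatory cytokine genes had 1 call among 21, IL6, from 0.459 ± 0.212 (n = 3) to 9.60 ± 10.97 CPM (n = 5), and 13 were higher adjusted over the list alone. In the camera test the adjusted p was 5.53e-04, 0.829 with an estimated correlation and 0.621 without resistant replicates 2 and 4. The fry adjusted p was 0.447. The list mean relative to vehicle was 0.01, 2.27, 0.57, 2.81 and 0.29 in resistant replicates 1 to 5. The immediate early genes JUNB and IER3 rose by 1.06 ± 0.23 and 1.21 ± 0.29, and KLF2 fell by 1.236. Adjusted over the list alone, 6 were higher and 2 lower. That list had a camera adjusted p of 0.0220, and 0.882 with an estimated correlation. It lost its call without vehicle replicate 2 (0.0566), resistant replicate 4 (0.174) or resistant replicate 5 (0.0540).

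Of 43 DNA replication genes none was called and 41 had a lower mean (median -0.28), with 0 lower adjusted over the list alone. The mitotic kinase gene PLK1 was the only call among 35 mitosis genes, at -0.73 ± 0.18, and the same 1 was lower adjusted over the list alone. Replication stress checkpoint genes had no call and 5 lower adjusted over the list alone. Camera adjusted p was 2.71e-05, 3.46e-04 and 5.25e-05 for these lists, and with an estimated correlation the adjusted p was 0.829, 0.882 and 0.464. The fry adjusted p was 0.360, 0.462 and 0.0896. The mitosis list lost its call without resistant replicate 4 (0.0684), in which its mean was -1.01 against -0.34 to 0.09 in the other resistant libraries. Without resistant replicates 2 and 4 the DNA replication list had an adjusted p of 0.172 and the mitosis list one of 0.678.

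Ribosomal protein genes had no call among 45 (median -0.21), with 0 adjusted over the list alone. MYC targets and ribosome biogenesis held 1 fall among 30, RRP9 at -0.55 ± 0.14, and 3 lower adjusted over the list alone. Both lists had a camera adjusted p of 5.25e-05, and with an estimated correlation it was 0.882 and 0.318. RRP9 lost its call with DESeq2-type size factors (adjusted p = 0.0502) and with no filter (0.0890). INSIG1, a brake on sterol synthesis, rose by 1.66 ± 0.38 and was the 1 call among 23 cholesterol synthesis genes, with 5 higher and 1 lower adjusted over the list alone. That list had a camera adjusted p of 0.00932, and 0.861 with an estimated correlation, and lost its call without resistant replicate 1 (0.0561) or 5 (0.104). CYP4F3, a cytochrome P450 gene, rose by 1.15 ± 0.18, the 1 call among 17 xenobiotic metabolism genes, with 2 higher adjusted over the list alone. Its list had a camera adjusted p of 0.0264, and 0.318 with an estimated correlation. It lost its call without vehicle replicate 1 (0.0775), vehicle replicate 2 (0.0647), resistant replicate 1 (0.0581), resistant replicate 3 (0.0524) or resistant replicate 5 (0.0647).

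Single genes with large rises included ZNF704 (ENSG00000164684, chromosome 8, 80628451 to 80874781), a zinc finger gene, from 0.420 ± 0.266 to 20.2 ± 15.7 CPM, at 5.57 ± 0.75. GLI2, a transcription factor of Hedgehog signalling, rose by 5.22 ± 1.03 and TNS1 by 5.09 ± 0.65 on the log2 scale. AUTS2, MME and PGBD5 rose by 4.44 to 4.56, with AUTS2 at 51.0 CPM in resistant replicate 4 and 1.58 to 17.1 in the others. KCNJ16, a potassium channel gene, had 1 count over the vehicle libraries, and its pooled CPM in resistant tumours was 276 times as high (95% counting interval 49.6 to 10913). That ratio rests in large part on resistant replicate 5, at 14.4 CPM against 0.412 to 7.04 in the others. Falls were largest in MMP16 at -4.63 ± 1.05, SOX21 at -4.12 ± 0.60, FYB1 at -3.64 ± 0.78, CPS1, an enzyme of the urea cycle, at -3.41 ± 0.66 and ID3 at -3.06 ± 0.76. NSG1, PRRG4 and SLC16A9 fell with -3.04, -2.66 and -2.60. All of these passed edgeR's test with adjusted p between 0.00527 and 0.0480.

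**Figure D2:**
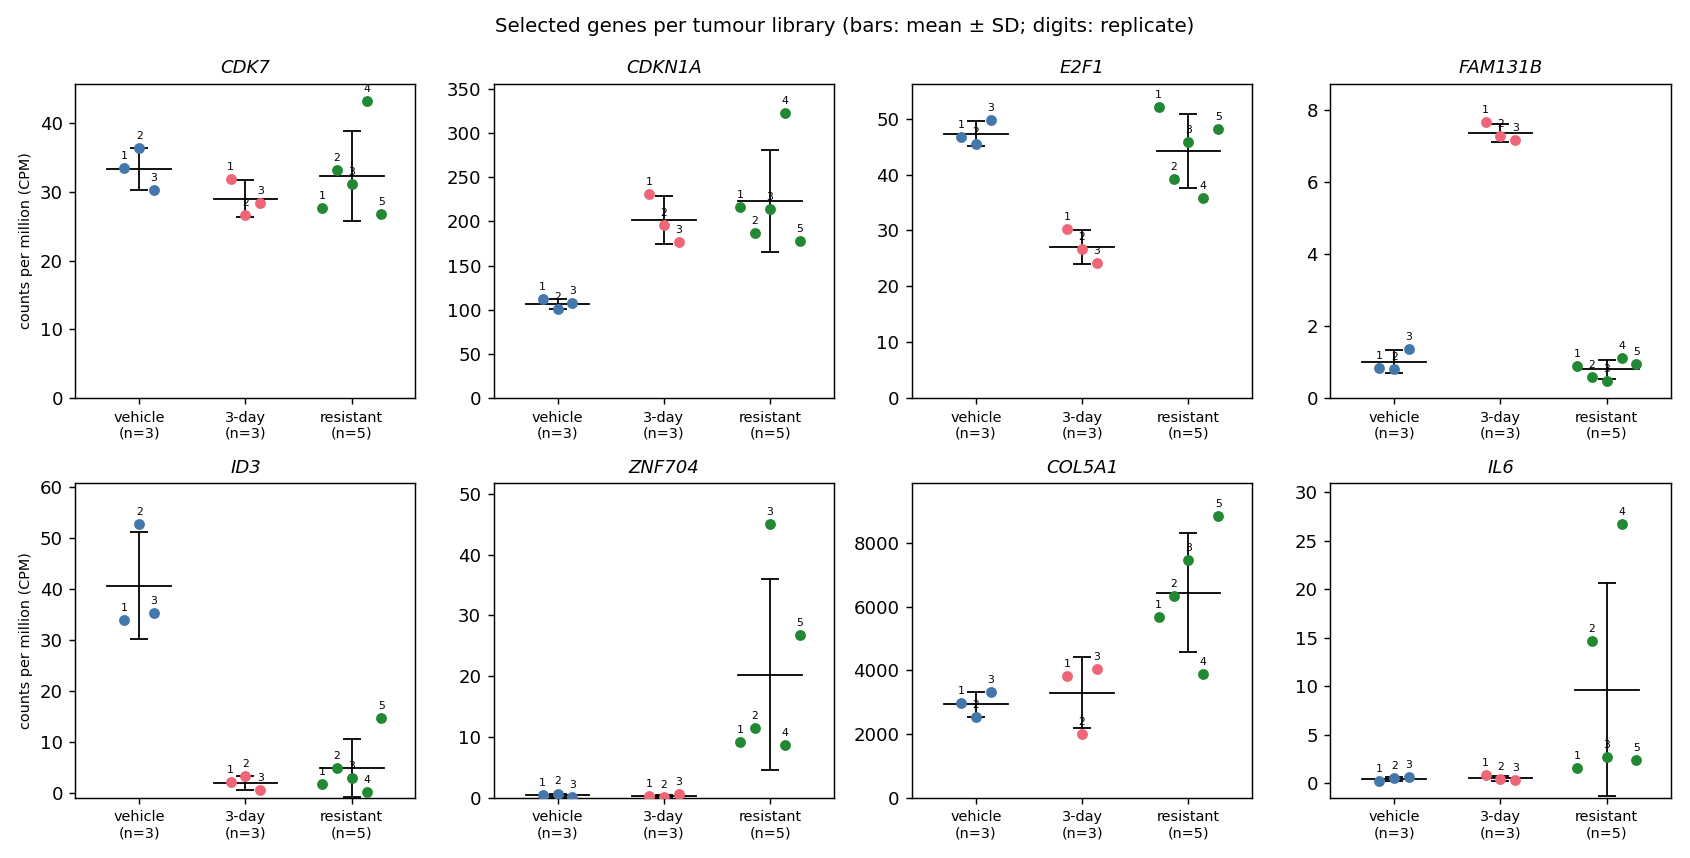
Expression of 8 genes in CPM (vertical axes, linear) in each tumour library by group (horizontal axes); points are libraries with their replicate number and bars are mean ± SD (n = 3 vehicle, 3 at 3 days, 5 resistant). FAM131B is at 7.37 ± 0.252 CPM at 3 days and 0.797 ± 0.258 in resistant tumours, while IL6 exceeds 10 CPM in resistant replicates 2 and 4.

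Comparing resistant with 3-day tumours asked which genes differed between both drug-treated groups. Genes of DNA replication (7 of 43 called), mitosis (5 of 35) and the ribosome (10 of 45) were higher in resistant than in 3-day tumours, and histone genes (10 of 23) were lower. With an estimated correlation these camera calls were lost, with an adjusted p of 0.587, 0.598, 0.587 and 0.339. DNA replication, mitosis and the ribosome missed the threshold by fry too (adjusted p = 0.128, 0.166 and 0.124). Resistant replicate 4 did not show the difference in the first pair of lists, with list means relative to vehicle of -0.87 and -1.01 against -0.85 to -0.81 and -0.84 to -0.68 at 3 days. Resistant replicate 3, at -0.70 for ribosomal protein genes, lay within the 3-day range of -0.87 to -0.40. Cholesterol synthesis genes (9 of 23, and 1 lower) and fibroblast markers (6 of 18) were higher too, calls also lost with an estimated correlation (adjusted p = 0.587 and 0.339). E2F1 was at 44.2 ± 6.58 CPM (n = 5) against 27.0 ± 3.06 (n = 3), a log2 fold change of 0.71 ± 0.15, and SQLE, which oxidises squalene, was at 110 ± 33.9 against 33.2 ± 4.10 CPM. CD274, which encodes the immune checkpoint ligand PD-L1, was at 5.68 ± 2.87 CPM in resistant and 29.3 ± 6.62 in 3-day tumours.

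Here 931 genes were called higher and 758 lower by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and 4734 had an unadjusted p under 0.05. A fit of only these 2 groups gave 317 and 221, with 537 of the 1689 calls kept, and DESeq2's Wald test gave 1464 and 1062. E2F1 had an adjusted p of 0.0141, SQLE one of 0.00326 and CD274 (ENSG00000120217, chromosome 9, 5450503 to 5470566) one of 0.00311. Without 3-day replicate 1, 2 or 3, 438, 511 and 428 of the 1689 calls remained, and without a resistant replicate 1138 to 1632 did. Without resistant replicate 4 the number called higher was 1405, and without resistant replicates 2 and 4 together it was 1414, with 1115 lower. Summed CPM of fibroblast markers was 5807 ± 1523 at 3 days (n = 3) and 12171 ± 2936 in resistant tumours (n = 5), and that of Schwann and neural markers 222 ± 31.5 and 336 ± 40.8, each with an exact permutation p of 0.0357 (adjusted 0.282). For macrophage and myeloid markers it was 96.9 ± 25.6 and 153 ± 47.3 (exact permutation p = 0.0714, adjusted 0.282). COL5A1 and COL1A1 made up most of the fibroblast sums in this comparison too.

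Of 43 DNA replication genes 7 rose and 17 were higher adjusted over the list alone, with POLA1, the catalytic subunit of polymerase alpha, at 1.08 ± 0.20 and GINS1 at 1.26 ± 0.28. Mitosis genes held 5 rises among 35, with NUF2 at 1.104 ± 0.22, BUB1B at 1.13 ± 0.25 and ASPM at 1.07 ± 0.27, and 6 higher adjusted over the list alone. Homologous recombination genes MRE11, RAD51D and NBN were the 3 rises among 31, at 1.08 ± 0.18, 1.097 ± 0.19 and 0.80 ± 0.14, with 8 higher adjusted over the list alone. By camera, the adjusted p was 1.43e-06, 1.60e-06 and 3.25e-05, and with an estimated correlation the adjusted p was 0.587, 0.598 and 0.587. For homologous recombination too, resistant replicate 4 (-0.54) lay within the 3-day range of list means, -0.65 to -0.52.

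Ribosomal protein genes held 10 rises among 45, with RPS20 at 0.94 ± 0.15, RPS4X at 0.81 ± 0.17 and RPS3 at 1.03 ± 0.22, and 22 higher adjusted over the list alone. Histone genes held 10 falls among 23, with HIST1H2BE at -1.48 ± 0.24, HIST1H2BK at -1.23 ± 0.21 and HIST1H4I at -1.16 ± 0.22, and 12 lower adjusted over the list alone. In the camera test the adjusted p was 6.39e-10 for both lists, and with an estimated correlation the adjusted p was 0.587 and 0.339.

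Cholesterol synthesis genes held 9 rises and 1 fall among 23. MVK and STARD4 rose by 1.17 ± 0.23 and 1.19 ± 0.24, whereas TM7SF2 fell with -1.19 ± 0.25. With p adjusted over the list alone, 16 were higher and 1 lower, with camera adjusted p of 1.85e-05 and 0.587 with an estimated correlation. Fatty acid synthesis genes FADS1, SCD and FADS2, all desaturases, rose by 1.96 ± 0.41, 1.44 ± 0.32 and 3.72 ± 0.93, with FADS2 at 109.8 CPM in resistant replicate 5 and 5.51 to 29.3 in the others. ELOVL1 went the other way at -0.44 ± 0.13, and lost its call with no filter (adjusted p = 0.100). Of 14 genes in that list 4 rose and 1 fell, with 5 and 1 adjusted over the list alone. Its camera adjusted p was 0.0323, and 0.587 with an estimated correlation, 0.0671 without 3-day replicate 3 and 0.0565 without resistant replicate 1.

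Among 18 fibroblast markers 6 rose and 11 were higher adjusted over the list alone, with LUM at 6.01 ± 0.83, COL6A3 at 1.80 ± 0.37 and PDGFRB at 1.57 ± 0.38. Camera adjusted p was 4.46e-05, and 0.339 with an estimated correlation. PDGFRB lost its call with no filter (adjusted p = 0.0546). NRF2 targets held 4 rises among 23, with AKR1C3 at 1.65 ± 0.26, FTH1 at 1.23 ± 0.25 and the haem oxygenase gene HMOX1 at 1.499 ± 0.38. When p was adjusted over the list alone, 13 were higher and 2 lower, with camera adjusted p of 0.00279 and 0.339 with an estimated correlation.

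Epithelial junction and keratin genes held 4 falls and 1 rise among 25. KRT18, EPCAM and KRT7, epithelial markers, had log2 fold changes of -0.94 ± 0.18, -1.17 ± 0.24 and -1.59 ± 0.32, and CLDN1, a tight junction gene, one of 1.83 ± 0.49. Adjusted over the list alone, 5 were lower and 1 higher, with camera adjusted p of 0.00337 and 0.587 with an estimated correlation. Resistant replicate 4 went the other way, with a list mean of 0.49 above the 3-day range of 0.06 to 0.36, against -0.63 to -0.12 in the other resistant libraries. NF-kB and cytokine genes held 7 rises among 21, with IL6 at 4.27 ± 1.02, CXCL6 at 5.85 ± 1.57 and IL1A at 3.51 ± 0.96, and 13 higher adjusted over the list alone. By camera, the adjusted p was 7.69e-04, 0.598 with an estimated correlation and 0.372 without resistant replicates 2 and 4. The fry adjusted p was 0.195 for this list and 0.133 for the epithelial list.

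Single genes with the largest rises included CCL2, a chemokine gene, at 6.56 ± 1.64, ZNF704 at 6.05 ± 0.80, UGT1A6 at 5.93 ± 1.69 and WISP1 at 4.73 ± 0.69. The value for CCL2 rests largely on resistant replicate 2, at 54.7 CPM against 0.424 to 7.69 in the others, and that for UGT1A6 on replicates 3 and 5 (12.07 and 25.1, against 1.60 to 2.33). KCNJ16 had 0 counts in all 3-day libraries and was at least 76.9-fold higher in resistant tumours, against a floor of 3 counts over the group, a bound that rests in large part on resistant replicate 5. COL10A1 and TM4SF18 had 1 and 2 counts over the 3-day libraries. Their pooled CPM in resistant tumours was 219 times (95% counting interval 39.3 to 8648) and 164 times as high (45.4 to 1353). Few libraries carry these ratios: COL10A1 was at 19.99 CPM in resistant replicate 5 and 0.617 to 2.11 in the others, and TM4SF18 at 15.4 and 18.9 in replicates 3 and 5 and 0.352 to 1.17 in the others. RPE65, NPTX1, FAM131B, SPOCD1 and NTSR1 had log2 fold changes of -3.65 ± 0.49, -3.44 ± 0.85, -3.21 ± 0.33, -3.02 ± 0.71 and -2.58 ± 0.62. NPTX1 was at 10.8 CPM in 3-day replicate 2 and 2.44 to 2.77 in the other 3-day libraries. In resistant tumours SPOCD1 was at 22.2 CPM in replicate 1 (0.769 to 8.49 in the others) and NTSR1 at 14.8 in replicate 4 (1.17 to 5.71). SPSB3 fell by 2.48, CD274 by 2.36 and TG, the thyroglobulin gene, by 2.20. All of these passed edgeR's test with adjusted p between 0.00108 and 0.0452.

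Set side by side, 102 genes were called in the same direction in 3-day and in resistant tumours against vehicle, 56 higher and 46 lower, and CDKN1A, FYB1, ID3, EGLN3, PFKFB3 and NUAK2 were among them. Independent lists would share 7.15 and 5.05 genes, which leaves out the shared vehicle libraries, so the excess is not a measure of a shared effect. In 20 simulations of unchanged groups 0 genes were shared, which their lack of effects sets beforehand, so that value cannot be held against the 102. The covariance of both log2 fold changes over 18040 genes was 0.227, against 0.110 ± 0.00245 (SD) in the simulations, in which only the shared vehicle libraries link them. The simulations gave all groups the same spread, whereas the median SD was 0.173 in vehicle and 0.404 in resistant tumours. The simulated 0.110 may therefore differ from what these vehicle libraries give. Genes were also drawn independently, so its SD leaves out their correlation. Pearson's r across genes was 0.396, below the simulated 0.558 ± 0.00698, so r by itself shows no link, and genes are not independent replicates. The 3 vehicle libraries are too few for parts of at least 2 and were not divided, so part of the excess may come from sharing them. Without vehicle replicate 1, 2 or 3, 2, 0 and 3 genes were shared. Without 3-day replicate 1 or 3, 18 and 4 were shared, and without resistant replicate 4 or 5, 178 and 172. With no filter on low counts 289 genes were shared. Of the 859 genes called at 3 days, 415 were also called between resistant and 3-day tumours. Both comparisons use the same 3-day libraries, and genes picked for a large 3-day change tend to differ toward the vehicle level by construction, so that count is no measure of a return. The median share of the 3-day change left in resistant tumours was 34.5%. A further 1075 genes called between resistant and 3-day tumours were called against vehicle in neither.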

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

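The tests on fibroblast markers and on the smaller changes in resistant tumours were chosen only after the results they address were seen; those on ribosomal protein genes and on splits of the samples were set before. Of the 10 splits of the 6 vehicle and 3-day samples, the real one called 859 genes and the highest other 0, and 10 splits are too few for a share under 0.05. Of the 56 splits of the vehicle and resistant samples 1, the real one, called as many as 517 genes, and the highest other called 463. Of the 56 splits of the 3-day and resistant samples 1, the real one, called as many as 1689, and the highest other called 274. In the latter pair of comparisons no other split called as many. That argues against chance only if the samples are separate animals, which the labels do not state. The 463 came from resistant replicates 3, 4 and 5 set against the other samples, so a split within the resistant group called nearly as many.

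Ribosomal protein genes were lower at 3 days, with a median log2 fold change of -0.63. To look for a bias, 295 other genes were matched on GC content, expression and the deposited gene length. That length (median 3393 bases for ribosomal protein genes and 3844 for matched genes) is not given as transcript length. A bias by transcript length is therefore not decided. The matched genes' median was 0.11 (95% bootstrap interval 0.07 to 0.16), which argues against a bias by GC content. This interval and the other bootstrap intervals below redrew genes with the libraries held fixed. They take genes as independent and leave out the spread between tumours. Reads moved to pseudogenes are argued against as well: summed CPM of 1142 ribosomal pseudogenes went from 482 ± 4.84 to 354 ± 33.5, and its change was -1.48% of the CPM lost from the genes. Leaving the 50 most abundant genes out of the scaling gave a median of -0.64 (-0.69 to -0.55), against a few genes taking more of the counts as the cause. A response to the drug stays open as a hypothesis, and RNA quality, for which the labels give no measure, was not tested.

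Fibroblast markers were higher in resistant tumours, with a list median of 0.85 and COL1A1 at 2098 ± 186 CPM in vehicle (n = 3) and 3766 ± 1130 in resistant tumours (n = 5). For COL1A1, host fibroblast reads are argued against by COL1A2, which those cells express abundantly. The change of COL1A2 was -0.119% of the CPM that COL1A1 gained. That reading assumes that mouse COL1A2 reads would align to the human gene as COL1A1 reads do. It does not cover the called markers COL5A1, COL6A3 and LUM. From vehicle to resistant tumours COL3A1 went from 18.7 ± 31.3 to 175 ± 332 CPM, with 766 in a resistant library. DCN went from 0.300 ± 0.260 to 0.564 ± 0.729 (at most 1.78) and SPARC from 2.72 ± 1.06 to 4.81 ± 5.72 (at most 14.9). For the list as a whole, host reads stay open. A lower share of tumour cells cannot be told apart from other sources, since 13 endothelial and myeloid markers had a median of 0.028 with an interval from -0.42 to 0.78, which holds 0 but also passes the bound set for the test, a rise of 50% of the fibroblast median. Expression by the tumour cells in the resistant state stays open and was not tested.

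Changes seen at 3 days were smaller in resistant tumours, with a median of 34.5% left. Picking the largest chance values at 3 days would give such a shrinkage, and a simulation of full retention was tried and replaced, since simulated bounds exclude nothing. Genes picked without 1 vehicle and 1 3-day library and measured in those left out kept 33.5% to 65.7% of the change over 9 choices, so the highest, 65.7%, was below 100%. Selection as the whole source is argued against. A weaker drug effect in resistant tumours, a difference in the time since the last dose, which the labels do not give, and a change in cell mixture stay open as untested.

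Among 142 values in the resistant group, 7 had a library far from the other 4. The ratio was not adjusted for the 142 values tested, so some or all of the 7 may pass by chance alone. Of the 5 genes among them, 4 were apart in replicate 4, which also stood apart on principal components 2 and 3. The ratio of gap to range, taken on log2 CPM for genes, was 0.725 for MNAT1 in replicate 4 (18.1 CPM against 11.4 to 12.97), 0.823 for ABCG2 in replicate 4 (1.03 against 0 to 0.0591), 0.720 for GINS3 in replicate 4 (3.98 against 7.10 to 8.87) and 0.738 for GINS1 in replicate 4 (14.8 against 32.4 to 42.8). It was 0.780 for RPE65 in replicate 5 (0.296 against 1.995 to 3.23). For summed markers, taken on CPM, it was 0.757 for endothelial cells in replicate 3 (41.6 against 68.5 to 77.1) and 0.832 for macrophages and myeloid cells in replicate 1 (237 against 121 to 140).

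Among genes named in a comparison with vehicle and called there, together with 3 called in both, differences between both treated groups with opposite signs against vehicle were called for 16 (resistant minus 3-day, log2 scale, edgeR). Genes outside that set, such as SPSB3, EPHA2, KRT7, POLA1 and MVK, also had opposite signs and a called difference. FAM131B was higher at 3 days and not in resistant tumours, with a difference of -3.21, and RRP9 had one of -0.59. Genes with a mean below vehicle at 3 days and above it in resistant tumours were PLEKHS1 with a difference of 4.34, WISP1 with 4.73, NUF2 with 1.104, RAD51D with 1.097, ZNF704 with 6.05, MME with 4.52, INSIG1 with 1.82, FTH1 with 1.23, AKR1C3 with 1.65 and LUM with 6.01. KCNJ16 had a fitted difference of 9.42, which depends on the default prior count of edgeR's fit since its 3-day libraries held 0 counts. For most of these, the change from vehicle was called in 1 of the groups alone. TNS3, ARHGEF10L and MSC were called in both, lower at 3 days (-0.77, -0.97 and -1.47) and higher in resistant tumours (0.69, 1.25 and 1.04), with differences of 1.46, 2.21 and 2.51. By median over a list, the difference was 1.44 for NF-kB and cytokine genes, 0.83 for cholesterol synthesis, 0.65 for NRF2 targets and 1.22 for fibroblast markers. These 4 camera calls were lost with an estimated correlation (adjusted p = 0.598, 0.587, 0.339 and 0.339), and that of NF-kB and cytokine genes without resistant replicates 2 and 4 (camera adjusted p = 0.372).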

How the results depend on the processing

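No called gene changed sign under another scaling or filter, with only the 2 groups, with the block or with 1 library left out. Groups did not overlap for 858 of 859, 513 of 517 and 1521 of 1689 called genes in the 3 comparisons. For those a turn of sign was hardly possible with a library left out. Counts of genes stayed within 1.5 times under DESeq2-type size factors, upper quartile scaling, the stricter filter and protein-coding genes only. DESeq2's Wald test gave 882 higher and 920 lower at 3 days, 875 and 461 in resistant tumours against vehicle, and 1464 higher against 3-day. With no filter, 790 were lower at 3 days, and 827 higher and 444 lower in resistant tumours, with 289 shared genes and a covariance of 1.08. A log2 fold change of at least 1 left 214 and 266, 203 and 120, and 498 and 299 genes (higher and lower in each comparison), by its construction. With only the 2 groups in the fit the counts were 1978 and 2080, 171 and 114, and 317 and 221. With the replicate number as a block they were 2212 and 2491 at 3 days and 182 and 107 between resistant and 3-day tumours, with 237 of the 1689 calls kept. The labels do not say that the numbers pair the samples. Without resistant replicates 2 and 4 together, chosen after seeing the data, 399 were lower than in vehicle and 1414 higher than at 3 days. The main fit takes a gene's spread to be the same in all groups. Its median SD within a group was 0.173 in vehicle, 0.269 in 3-day and 0.404 in resistant tumours. The simulated data held the same assumption, so their false calls do not cover a breach of it. Whether this caused the shifts was not tested.

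Leaving out in turn each library of the compared groups gave 1 to 274 genes higher and 0 to 226 lower at 3 days, 0 to 424 and 1 to 309 in resistant tumours against vehicle, and 245 to 1405 and 200 to 1120 against 3-day. For these counts, libraries of the group outside a comparison, which share its fit, were not left out singly. With any library of all groups left out, shared genes ran from 0 to 178 and the covariance from 0.196 to 0.412. For these fits, and with no filter, no covariance of unchanged groups was simulated, so they cannot be set against the value for all libraries. A group left with 2 libraries has less power by construction.

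Of the list calls, 136 values lost the threshold and 461 kept it: an estimated correlation ended all 46, fry 31, DESeq2-type size factors 1 (MAPK output, 0.0510), the replicate block 5 and only the 2 groups 2. Leaving out resistant replicates 2 and 4 ended 10 of them. Of the named gene results, 1851 were the same, 546 lost and 14 gained a call. Signs turned in 15, none of them called, where a library was left out. Log2 fold changes then ran from -0.12 to 0.24 for MYC at 3 days, and in resistant tumours against vehicle from -0.17 to 0.018 for CDK7, -0.33 to 2.26 for ABCB1 and -0.24 to 0.59 for ABCG2. Against 3-day they ran from -0.021 to 0.26 for CDKN1A and -0.093 to 0.049 for CCNH. ABCB1 and ABCG2 were under 1 CPM, where depth limits any reading.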

Other observations

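The tests on histone genes were chosen only after their result was seen. Several lists had a smaller change with few called members. At 3 days, unfolded protein response chaperones (median -0.33) and cholesterol synthesis genes (median -0.32) were lower and mitochondrially encoded genes (median 0.22) higher, with no member called over all genes or adjusted over the list alone. Interferon response genes were lower (median -0.34), with IFI44 falling by 2.18 and ISG15, an interferon-induced modifier, rising by 1.40, and with 2 higher and 3 lower adjusted over the list alone. In the camera test the adjusted p was 0.0167, 0.0382, 0.0167 and 0.0382 for these lists, and with an estimated correlation the adjusted p was 0.593 for all 4. Calls were lost for cholesterol synthesis without vehicle replicate 3 (0.144), 3-day replicate 1 (0.0903) or 3-day replicate 2 (0.0556), for interferon without vehicle replicate 2 (0.130), 3-day replicate 1 (0.0972) or 3-day replicate 3 (0.200), and for mitochondrial genes without 3-day replicate 1 (0.0972). In resistant tumours against vehicle, heat shock genes were lower (median -0.38, camera adjusted p = 0.0220, and 0.745 with an estimated correlation), with none called, 1 higher and 5 lower adjusted over the list alone, and an adjusted p of 0.123 without resistant replicate 1.

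Between resistant and 3-day tumours, EPHA2, a receptor kinase, and the AP-1 gene FOSL1 were the 2 falls among 16 MAPK output genes, at -1.07 ± 0.15 and -0.85 ± 0.22, with 3 lower adjusted over the list alone. That list had a camera adjusted p of 0.0499, and 0.587 with an estimated correlation, and its mean in resistant replicate 4 (0.52) was above the 3-day range (0.12 to 0.39). It was lost without 3-day replicate 1 (0.0842) or 2 (0.0857) or resistant replicate 1 (0.147), 2 (0.159) or 3 (0.0533). SEL1L, of protein degradation in the endoplasmic reticulum, rose by 0.60 ± 0.17, the 1 call among 18 chaperones, with 0 adjusted over the list alone. SAMD9L, IFI44 and EPSTI1 rose by 1.07, 1.54 and 0.85 while ISG15 fell with -0.71 ± 0.18, and adjusted over the list alone 4 of the 34 interferon response genes were higher and 1 lower. LOX and PGK1 rose by 2.32 ± 0.36 and 0.54 ± 0.15 among 28 hypoxia genes, with 2 adjusted over the list alone. MT-ND3 was the 1 fall among 15 mitochondrial genes, at -0.62 ± 0.16, and also adjusted over the list alone, and 5 Schwann and neural markers had no call, with 3 higher adjusted over the list alone. Camera adjusted p was 0.0323, 0.0430, 0.0258, 0.0246 and 0.0117 for chaperones, interferon, hypoxia, mitochondrial genes and Schwann markers, and with an estimated correlation the adjusted p was 0.689, 0.671, 0.689, 0.671 and 0.340. Calls were lost for chaperones without 3-day replicate 1 (0.0726) or resistant replicate 1 (0.0714) or 4 (0.285), for interferon without 3-day replicate 1 (0.120) or 3 (0.267) or resistant replicate 1 (0.101), 2 (0.129) or 4 (0.0994), for hypoxia without 3-day replicate 2 (0.375) or resistant replicate 2 (0.0691) or 4 (0.230), for mitochondrial genes without 3-day replicate 1 (0.150) or resistant replicate 2 (0.129), and for Schwann markers without 3-day replicate 2 (0.0561). EPSTI1 lost its call under upper quartile scaling (0.0531).

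Lists that were not called by camera in any comparison, beside the TFIIH list, included p53 targets (adjusted p = 0.450, 0.357 and 0.918), transcriptional kinases and elongation (0.191, 0.896 and 0.232), ABC efflux transporters (0.491, 0.727 and 0.918) and the classical (0.780, 0.858 and 0.605) and basal-like (0.783, 0.968 and 0.771) pancreatic tumour subtypes. A p that misses the threshold does not show that these genes were alike in all groups.

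Antisense transcripts held 38 rises and 5 falls among 1321 tested at 3 days and long intergenic RNAs 20 rises and 8 falls among 1006, while protein-coding genes held 322 rises and 417 falls among 13822. Reads of overlapping genes cannot be assigned to a strand here, so the antisense counts are uncertain.

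A hypothesis for the higher histone transcripts at 3 days was a larger share of cells in S phase, in which replication genes would be higher as well. Their median log2 fold change was -0.79 (95% bootstrap interval over genes, not libraries, -0.91 to -0.68), so they were not higher. That fall was already known when the test was chosen. The drug could also lower these transcripts whatever the share of cells in S phase, so the test does not decide the question. Another hypothesis was that a family of transcription factors moved as a group at 3 days. With the preset correlation camera called 3 of 17 families, all lower: E2F (adjusted p = 0.00165), HMG (0.00668) and Homeobox (0.00668). With an estimated correlation the lowest adjusted p was 0.0570. The outcome set beforehand as counting against the hypothesis, no family under 0.05 with an estimated correlation, was met, but that criterion was wrong, because a p that misses the threshold excludes nothing, so the question stays open.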
